A study of Medicago truncatula with 8 samples.

How the data were processed

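RNA was measured in transformed Medicago truncatula roots of 4 groups, EV mock, EV inoculated, OX390 mock and OX390 inoculated, with 2 libraries each, taken 48 hours after water or S. meliloti. Per the labels' protocols, libraries were made from polyadenylated RNA with a kit that does not mark the strand, and sequenced as single reads of 76 nt. The deposited values are estimated counts per gene and library, made by the authors with HISAT2 alignment and StringTie, per the submitters' processing notes and the file headers. The values are whole numbers and unscaled, and StringTie derives them from read coverage. The notes also list DESeq2, with no output of it deposited. Versions, the genome build and the strand setting are not given in the sources used here, so no coordinates are printed.

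The table holds 62300 entries. Of these 52705 carry a reference ID, 3685 of them with a short gene name, and 9595 hold only an assembly ID (MSTRG), with 14.5% to 19.4% of the counts of a library. The reference table given for this organism could not be linked to these IDs, so names are those in the files. An MSTRG locus can hold several entries, and 9290 of the 50461 loci do, with 21129 entries. A locus sum below is the sum of the counts of all entries of a locus.

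All computing here started from the deposited counts, in R 4.3.3. Entries were kept by edgeR's filterByExpr by group (34837 entries, and 26263 locus sums), scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests (glmQLFit and glmQLFTest, design of 4 groups, Benjamini-Hochberg adjusted p under 0.05). The 7 contrasts are inoculation in EV, inoculation in OX390, OX390 in mock, OX390 in inoculated roots, the interaction, and the averages over both vectors and over both states. If nothing differed, about 5% of genes would have an unadjusted p under 0.05. Of entries, 5.13%, 3.58%, 3.30%, 2.25% and 2.45% did in this order up to the interaction. For average inoculation it was 7.01% and for average OX390 3.53%. Counts at or below 5% thus point to no pool of changed genes. All 8 libraries share the estimate of the spread, and the biological coefficient of variation was 0.632 for entries and 0.313 for locus sums. The groups differed in spread. Chi-square per degree of freedom between a group's libraries was 94.3 in EV mock and 65.2 in OX390 mock. It was 32.1 in EV inoculated and 18.5 in OX390 inoculated roots (locus sums). A shared spread can thus understate the error of the mock groups. The EV mock libraries correlated at 0.930, below the highest match of each outside the group (0.949 and 0.963). The tests, most alternatives and the themes of the planned gene lists were chosen before the data were examined. Locus sums and the alternatives built on them were chosen after seeing the data, as was the fit on named entries alone. The replicates are known to be separate samples from the labels only, so the p-values measure the spread between these samples. Intervals and limits of a count of 0 cover counting error only. A lone library left by leaving out its partner is assumed to vary like the other groups.

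Folds against a group with 0 counts are lower bounds against 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as other tools.

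Gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, with an estimated correlation, and with fry, adjusted over lists within a contrast. Of 217 pairs of list and contrast, 39 passed with the preset correlation, 0 with an estimated correlation and 6 with fry, and 55 as locus sums with the preset correlation. The planned lists matched gene descriptions, which the files lack. They were therefore rewritten as gene symbols, from names alone and without looking at values: 22 lists come from the planned themes (the planned defence list was divided into pathogenesis-related proteins and β-1,3-glucanases), 10 were added from the names found, and 7 planned lists were dropped for lack of named genes. The resulting 32 lists are Nod factor signalling and infection, nodulins, late nodule genes, CLE and CEP peptides and autoregulation, cytokinin, auxin response factors, early auxin response, auxin carriers, LBD, small RNA pathway, gibberellin, ethylene, strigolactone, phenylpropanoid and flavonoid synthesis, pathogenesis-related proteins and defensins, β-1,3-glucanases, class III peroxidases, cell cycle, nitrate, phosphate transport, fermentation and phytoglobins, and abscisic acid and dehydration. The added ones are auxin synthesis, root meristem, arbuscular mycorrhiza, vascular, sugar transporters, aquaporins, cysteine proteases and senescence, non-specific lipid transfer proteins, and chloroplast-encoded and mitochondrion-encoded transcripts. Lists with at least 5 tested members were tested, which gave 31. Where members are adjusted over the list alone, this was done within each list and contrast. It was not corrected over the 217 pairs, so some such passes can arise by chance. List medians did not change when genes with a group at 0 were set to their bound.

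Named genes follow a rule with 3 parts. The first takes, per contrast, up to 6 highest and 6 lowest fold changes (4 and 4 for the interaction) among called genes with a product name, a mean log2 CPM of at least 1 and no overlap between sides (not asked of the interaction), and gave 0 genes as entries and 4 as locus sums (MtD27, MtNFH1, MtSPK1 and MtSRL1). The second takes up to 4 members with the smallest p of each called list. The third takes MtNIN, MtNSP1, MtNSP2, MtERN1, MtNF-YA1, MtENOD11, MtNPL, MtCHK1/MtCRE1, MtRRA4;MtRR4, MtCLE13, MtSUNN, MtLBD16, ARF2, ARF3 and ARF4 genes, and miR390 and TAS3 genes. All other named genes were chosen after their values were seen.

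The steps were tested on simulated data, with counts drawn from the means of the real genes and 200 genes changed by 2, 4 or 8-fold. At 8-fold, edgeR recovered 9.09% of changed entries for inoculation in EV roots, 0% for the other 3 comparisons of 2 groups and for the interaction, 33.8% for the average OX390 effect and 42.2% for the average inoculation effect. For locus sums these values were 73.7% for inoculation in EV, 70.6% for inoculation in OX390, 64.6% for OX390 in mock, 68.9% for OX390 in inoculated roots, 42.1% for the interaction, 87.9% for the average OX390 effect and 89.7% for the average inoculation effect. Of the calls on locus sums, 8.16%, 8.42%, 11.1%, 7.59%, 10.3%, 9.15% and 5.88% in the same order were of genes left unchanged, above the 5% aimed at. Each value comes from a single draw. An earlier draw, with the loci in another order, gave other values for locus sums, furthest apart for the interaction, so they are rough. Alternatives were DESeq2 size factors, no filter, a stricter filter (2 CPM in 2 libraries), a fold change minimum, the libraries of 2 groups alone, an additive model, the replicate number as a block, and leaving out each library.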

Results

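Gene counts were measured in roots of the legume Medicago truncatula (genotype Jemalong A17) transformed with Agrobacterium rhizogenes, which induces transgenic hairy roots. The roots carried an empty vector (EV) or a vector that overexpresses the microRNA miR390 (OX390). They were given water (mock) or the nitrogen-fixing symbiont Sinorhizobium meliloti after 7 days without nitrogen, and were sampled 48 hours later. Each of the 4 groups has 2 libraries, numbered 1 and 3 in the labels. Total counts were 21192847 and 25481335 in EV mock, 15014646 and 30140866 in EV inoculated, 18395654 and 26237403 in OX390 mock, and 17158067 and 24693277 in OX390 inoculated roots. A count of 0 therefore allows up to 0.0995 to 0.200 CPM (counts scaled to a common library total) in a library, taking 3 counts as the limit. Expression is given below as CPM, mean ± SD over the libraries of a group (n = 2), or over 4 libraries where both vectors or both inoculation states are pooled.

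miR390 directs the cleavage of TAS3 transcripts, and the small RNAs made from them target mRNAs of auxin response factors (ARF2, ARF3 and ARF4). The overexpression could not be read from these counts. The files name no miR390 gene, and the entry named MtTAS3 had 0 counts in 8 of 8 libraries. The assignment of libraries to vectors thus rests on the labels. Among the ARF entries, MtARF4;MtARF7; MtARF4b was at 14.5 ± 5.37 CPM in EV inoculated and 6.84 ± 0.139 CPM in OX390 inoculated roots, a log2 fold change of −1.08 (SE 0.41) that did not pass (edgeR adjusted p = 1). Its locus sum, which adds the other entry of that locus, differed by −0.22 (SE 0.22). Over both inoculation states the OX390 minus EV log2 difference was 0.17 (SE 0.12) for MtARF3 (MSTRG.20210), −0.07 (SE 0.16) for MtARF2;MtARF23 and 0.32 (SE 0.27) for MtARF2, whose locus sum gave −0.15 (SE 0.20). For MtARF12; MtARF4a it was 0.38 (SE 1.27) for the entry and −0.26 (SE 0.13) for the locus sum. The value of MtARF2;MtARF23 turned to 0.05 without OX390 mock replicate 1, and that of the entry MtARF12; MtARF4a to −0.12 without EV mock replicate 1. MtARF4 and MtARF3 (MtrunA17Chr2g0277461) had 0 counts in every library.

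The transcription factor gene MtLBD16, of the LBD family, a member of which the series title places under the miR390 pathway, lay at 3.97 ± 1.97 CPM in EV mock, 8.85 ± 1.30 CPM in EV inoculated, 5.90 ± 0.633 CPM in OX390 mock and 8.10 ± 0.0706 CPM in OX390 inoculated roots. Its log2 fold change on inoculation was 1.16 (SE 0.43) in EV and 0.46 (SE 0.42) in OX390 roots, and the difference between these, −0.70 (SE 0.60), did not pass (edgeR adjusted p = 1). The OX390 minus EV difference over both states was 0.22 (SE 0.30) for MtLBD16, 0.33 (SE 0.33) for MtNIN, 0.07 (SE 0.42) for MtNF-YA1, 0.47 (SE 0.41) for MtERN1, 0.33 (SE 0.28) for MtNSP1 and 0.70 (SE 0.41) for MtNSP2, and each had an edgeR adjusted p of 1. The value of MtNF-YA1 turned to −0.16 without EV inoculated replicate 3 and to −0.13 without OX390 inoculated replicate 1. It was also negative without EV mock replicate 1 (−0.07) and without OX390 mock replicate 3 (−0.0049).

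The average inoculation effect asks what S. meliloti changed over both vectors, with 4 inoculated against 4 mock libraries. The transcription factor gene MtNIN, which is required for infection and nodule formation, rose from 0.478 ± 0.136 CPM in mock to 7.07 ± 2.11 CPM in inoculated roots (locus sum log2 fold change 3.84, SE 0.31, edgeR adjusted p = 0.0140). The pectate lyase gene MtNPL had 0 counts in the 4 mock libraries and 6.60 ± 2.78 CPM in the inoculated ones, at least 186-fold higher as a locus sum against 3 counts over the mock group (edgeR adjusted p = 0.0140). MtCBS1 was at least 148-fold higher (edgeR adjusted p = 0.0140) and the lipid transfer protein gene MtnsLTP62 at least 305-fold higher (edgeR adjusted p = 0.0135). The entry named MtENOD11 antisense had 3 counts over the mock libraries and 18.9 ± 4.95 CPM in inoculated roots, a ratio of 537 with a 95% counting interval of 183 to 2607 (edgeR adjusted p = 0.00751). The library kit does not mark the strand, so these reads are not shown to be antisense.

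**Figure D1:**
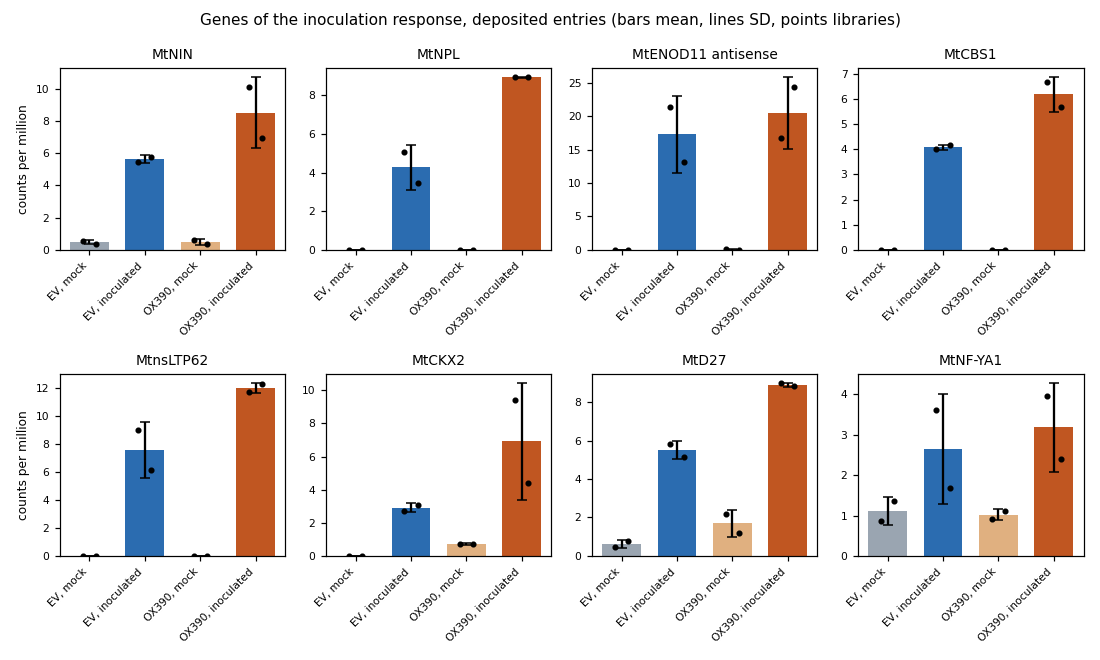
Expression of 8 genes in the 4 groups, in CPM on the vertical axis, as deposited entries; bars give the mean, lines the SD and points the 2 libraries of each group. MtNIN lies at 0.467 and 0.489 CPM in the mock groups and at 5.62 and 8.51 CPM in the inoculated groups, and MtNPL, MtCBS1 and MtnsLTP62 are at 0 in every mock library.

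Further genes rose as locus sums. The β-carotene isomerase gene MtD27, of strigolactone synthesis, rose from 1.15 ± 0.751 to 7.20 ± 1.98 CPM (log2 fold change 2.76, SE 0.29, edgeR adjusted p = 0.0304), and the Nod factor hydrolase gene MtNFH1 rose by 2.78 (SE 0.29, edgeR adjusted p = 0.0288). The cytokinin oxidase gene MtCKX2 had 0 counts in EV mock, 0.720 ± 0.0380 CPM in OX390 mock and 4.91 ± 3.09 CPM in the inoculated libraries (edgeR adjusted p = 0.0260). MtSPK1 rose by 2.03 (SE 0.18) and MtSRL1 by 1.97 (SE 0.20) on the log2 scale, with edgeR adjusted p = 0.0154 and 0.0260. MtABAB35 rose by 3.57 (SE 0.30, edgeR adjusted p = 0.0148), and MtABAB14 went from 0.0912 ± 0.106 to 3.36 ± 1.12 CPM (edgeR adjusted p = 0.0140). MtCYM1 and MtPCY16;MtSC15 were at least 95.6-fold and 78.5-fold higher than in mock roots, where both had 0 counts (edgeR adjusted p = 0.0260 for each). Of the loci that fell, 2 chosen after their values were seen are MtrunA17Chr4g0008791 (log2 fold change −1.21, SE 0.14, edgeR adjusted p = 0.0455), and MtrunA17Chr8g0376891 (−4.47, SE 0.49, edgeR adjusted p = 0.0375). MtNF-YA1 missed the threshold with a locus sum difference of 1.98 (SE 0.26, edgeR adjusted p = 0.0702), as did MtERN1 with 0.90 (SE 0.38), MtNSP1 with 0.60 (SE 0.25), MtNSP2 with 1.05 (SE 0.36) and MtLBD16 with 0.79 (SE 0.25). The entry named MtENOD11 had 0 counts in mock roots and 0.427 ± 0.346 CPM in inoculated roots, at least 10.8-fold higher (edgeR adjusted p = 0.334). As the kit does not mark the strand, MtENOD11 reads may also be counted in the entry named MtENOD11 antisense. The value of this entry alone thus does not show how far the gene rose.

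As locus sums, edgeR called 21 loci up and 3 down of 26263 in this comparison (2358, or 8.98%, at an unadjusted p under 0.05), DESeq2 563 and limma-voom 19. As deposited entries, edgeR called 6 up and 2 down of 34837 (2441, or 7.01%, at an unadjusted p under 0.05), DESeq2 876 and limma-voom 0. MtNIN, MtNPL, MtCBS1, MtnsLTP62, MtCKX2, MtABAB14, MtABAB35, MtSPK1, MtSRL1, MtD27, MtNFH1, MtCYM1, MtPCY16;MtSC15 and MtENOD11 antisense did not pass in edgeR as entries (MtNIN adjusted p = 0.124, MtD27 adjusted p = 0.185) and passed in DESeq2 (MtNIN adjusted p = 1.11e-16, MtD27 adjusted p = 2.69e-10). With the replicate number as a block, 4 of the 24 loci stayed called, and 0 entries were called. The 24 loci kept their direction without each library in turn. Of them, 3 stayed called without EV inoculated replicate 1, 3 without EV inoculated replicate 3, 15 without OX390 mock replicate 1, 3 without OX390 inoculated replicate 1, and 0 without OX390 mock replicate 3 or OX390 inoculated replicate 3, while 158 loci were called without EV mock replicate 3. The 8 called entries became 1 without OX390 mock replicate 3 and 0 without any other library.

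Gene lists were tested with camera over both vectors. The Nod factor signalling and infection list rose, with 21 of 26 members positive, a median log2 fold change of 0.37 and camera adjusted p = 7.57e-08 (adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, 5 members passed in edgeR and 0 over all entries: MtNPL, MtCBS1, MtNIN, MtFLOT4 and MtNF-YA2. For MtNF-YA2 the log2 fold change was 6.75 as an entry and −0.06 as a locus sum, so the locus as a whole did not rise. Nodulins rose, with 15 of 20 positive, a median of 0.68 and camera adjusted p = 1.37e-05 (adjusted p = 0.159 with an estimated correlation, 0.614 with a stricter expression filter). Of these, 7 passed adjusted over the list alone and 0 over all entries, among them MtENOD12 (at least 24.3-fold higher) and MtN1c (3.12, SE 0.65). Another of the 7, MtENOD8.2, differed by 0.95 as an entry and by 0.23 as a locus sum (MtENOD8.2 + MtENOD8.3 + MtrunA17Chr1g0160001). Both lists also moved up in fry (adjusted p = 0.00341 for each). Aquaporins fell as a list, with 7 of 7 negative, a median of −0.58 and camera adjusted p = 0.00140 (adjusted p = 0.677 with an estimated correlation). MtTIP1g passed adjusted over the list alone, with 0 members over all entries. It lay at 1.16 ± 0.217 CPM in mock and 0 counts in inoculated EV roots, and at 1.03 ± 0.235 and 0.793 ± 0.498 CPM in OX390 roots. Adjusted over the list alone it passed in EV roots (adjusted p = 0.00824) and in the interaction (adjusted p = 0.0206), while its log2 difference in OX390 roots was −0.37 (SE 0.72).

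CLE and CEP peptide and autoregulation genes fell, with 33 of 47 negative, a median of −0.26 and camera adjusted p = 0.00860 (adjusted p = 0.714 with an estimated correlation). MtCEP9 lay at 29.0 ± 10.7 CPM in mock and 12.4 ± 3.23 CPM in inoculated roots. β-1,3-Glucanases fell as a list, with 26 of 36 negative, a median of −0.24 and camera adjusted p = 0.00730 (adjusted p = 0.682 with an estimated correlation). MtBG14 lay at 97.8 ± 27.95 and 64.7 ± 7.31 CPM. Non-specific lipid transfer proteins fell, with 38 of 44 negative, a median of −0.37 and camera adjusted p = 0.00860 (adjusted p = 0.677 with an estimated correlation), although MtnsLTP62 was far higher and 2 members rose adjusted over the list alone, and fry gave the other direction (adjusted p = 0.879). No member of the peptide and glucanase lists passed adjusted over the list alone or over all entries. Without EV mock replicate 3 the adjusted p of these 3 lists became 0.395, 0.331 and 0.0691, without EV inoculated replicate 1 it became 0.0863 for each, and without OX390 mock replicate 1 it became 0.258, 0.0576 and 0.120. The peptide list also lost its call without OX390 inoculated replicate 3 (0.181) and with the stricter filter (0.0796).

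In EV roots alone, the comparison of inoculated with mock libraries asks what S. meliloti changed in control roots. MtNIN lay at 0.467 ± 0.119 CPM in mock and 5.62 ± 0.234 CPM in inoculated roots, and MtNPL, MtCBS1 and MtCKX2 had 0 counts in mock and were at least 60.5-fold, 61.8-fold and 44.8-fold higher in inoculated roots as entries. The Nod factor signalling and infection list rose, with 24 of 26 members positive (median 0.69, camera adjusted p = 1.48e-10, adjusted p = 0.118 with an estimated correlation), with 3 members past the threshold adjusted over the list alone (MtNPL, MtNIN and MtCBS1) and 0 over all entries. Nodulins rose as a list, with 14 of 20 positive (median 1.08, camera adjusted p = 5.38e-05, adjusted p = 0.118 with an estimated correlation, 0.588 with a stricter filter), with 0 members past it in either adjustment. The CLE and CEP peptide list fell, with 34 of 47 negative (median −0.31, camera adjusted p = 0.0338, adjusted p = 0.882 with an estimated correlation), with MtCLE43 at 1.82 ± 0.556 and 0.629 ± 0.0983 CPM. With edgeR 0 of its members passed adjusted over the list alone or over all entries, and 4 were lower at an unadjusted p under 0.05. That call was lost without EV mock replicate 3 (0.896, with the camera direction turned), without EV inoculated replicate 1 (0.333) and with the stricter filter (0.0986). As entries edgeR called 0 (1787, or 5.13%, at an unadjusted p under 0.05), DESeq2 658 and limma-voom 0. As locus sums edgeR called MtrunA17Chr6g1025401, chosen after its values were seen, at 0 counts in mock and 103 ± 11.7 CPM in inoculated roots, at least 1557-fold higher (adjusted p = 0.00915). DESeq2 called 400 locus sums and limma-voom 0, and edgeR called 186 without EV mock replicate 3 and 0 without either EV inoculated or either OX390 mock library.

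Organelle transcripts were tested as lists in the same comparison. The libraries were made from polyadenylated RNA, and how far that selection keeps organelle RNA was not measured. Changes in these lists are therefore not shown to be changes of organelle expression. The list of chloroplast-encoded transcripts fell in EV roots, with 67 of 73 members negative (median −1.26, camera adjusted p = 2.79e-05, adjusted p = 0.882 with an estimated correlation) and so did that of mitochondrion-encoded transcripts, with 90 of 114 negative (median −0.43, camera adjusted p = 9.49e-04, adjusted p = 0.902 with an estimated correlation). With edgeR 0 members of either list passed adjusted over the list alone or over all entries, and 0 were at an unadjusted p under 0.05. The chloroplast share of counts was 0.0644% and 0.01002% in the EV mock libraries 1 and 3, 0.0314% and 0.00500% in EV inoculated, 0.0152% and 0.00797% in OX390 mock, and 0.0419% and 0.0122% in OX390 inoculated libraries, higher in number 1 in 4 of 4 groups. The mitochondrial share was 0.104% and 0.0324%, 0.101% and 0.0180%, 0.0458% and 0.0257%, and 0.0644% and 0.0275% in the same order. Within each number, both shares were lower in inoculated than in mock EV roots, and higher in inoculated than in mock OX390 roots. Leaving out an EV library unbalances the numbers 1 and 3, so the turns that follow also carry the difference by number. In EV roots the camera direction of both lists turned without EV mock replicate 1 (adjusted p = 0.679 for each, medians 0.73 and 0.73) and without EV inoculated replicate 3 (0.772 and 0.00212, medians −0.53 and 0.39).

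In OX390 roots the same question was asked of the overexpressing roots. MtNIN lay at 0.489 ± 0.202 CPM in mock and 8.51 ± 2.21 CPM in inoculated roots, and MtNPL, MtCBS1 and MtnsLTP62 had 0 counts in mock and were at least 129-fold, 88.2-fold and 174-fold higher as entries. The Nod factor list rose, with 19 of 26 members positive (median 0.29, camera adjusted p = 6.58e-04, adjusted p = 0.581 with an estimated correlation), with 3 members past the threshold adjusted over the list alone (MtNPL, MtNIN and MtCBS1) and 0 over all entries. Nodulins rose as a list, with 14 of 20 positive (median 0.73, camera adjusted p = 1.90e-04, adjusted p = 0.243 with an estimated correlation, 0.613 with a stricter filter). Adjusted over that list alone, 4 nodulins rose and MtN13 fell, from 3.22 ± 0.0121 to 0.164 ± 0.00124 CPM, with 0 over all entries. Chosen after their values were seen, the 4 entries that edgeR called of 34837 were MtrunA17Chr6g1025401, which fell to 0 counts, and MSTRG.14225, MSTRG.26939 and MtrunA17Chr6g0463451, each at 0 counts in OX390 mock alone (adjusted p = 0.0406 for each). The last 3 are entries of loci whose sums differed by 0.17, 0.44 and −0.09 on the log2 scale. There were 1246 entries (3.58%) at an unadjusted p under 0.05, DESeq2 called 374 and limma-voom 0. Without OX390 mock replicate 3 edgeR called 2 entries, and 0 without any other library. As locus sums edgeR called MtrunA17Chr6g1025401 down, and MtrunA17Chr8g0354001 (adjusted p = 0.0188) and MtrunA17Chr6g0482231 (log2 3.72, adjusted p = 0.0252) up, DESeq2 called 122 and limma-voom 0. Of the locus sums, 16 were called without EV mock replicate 1, 11 without EV mock replicate 3, 6 without OX390 mock replicate 1, and 0 without either EV inoculated library, OX390 mock replicate 3 or OX390 inoculated replicate 3.

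The list of nitrate uptake and reduction genes fell upon inoculation in OX390 roots, with 11 of 11 members negative (median −1.20, camera adjusted p = 7.01e-04, adjusted p = 0.850 with an estimated correlation). With edgeR 0 members passed adjusted over the list alone or over all entries, and 3 were lower at an unadjusted p under 0.05. MtNRT2.1, a high-affinity nitrate transporter gene, lay at 68.8 ± 87.3 CPM in mock and 3.98 ± 0.493 CPM in inoculated roots, with 122 and 3391 counts in the OX390 mock libraries 1 and 3. Also lower as lists were aquaporins with 7 of 7 negative (median −0.56, camera adjusted p = 0.00167), β-1,3-glucanases with 26 of 36 (median −0.26, camera adjusted p = 0.00638), lipid transfer proteins with 38 of 44 (median −0.49, camera adjusted p = 0.00516) and sugar transporters with 20 of 30 (median −0.26, mean 0.11, camera adjusted p = 0.0425). Each of these had adjusted p = 0.850 with an estimated correlation, and of their members MtnsLTP62 alone passed adjusted over its list alone, with 0 over all entries. MtTIP1d lay at 82.0 ± 25.3 and 43.4 ± 2.37 CPM, MtBG14 at 120.0 ± 17.4 and 70.1 ± 3.19 CPM, and MtSTP13 at 63.7 ± 3.78 and 39.1 ± 1.55 CPM. The list of chloroplast-encoded transcripts rose, with 66 of 73 positive (median 1.29, camera adjusted p = 6.58e-04, adjusted p = 0.850 with an estimated correlation), and with edgeR 0 members passed in either adjustment or at an unadjusted p under 0.05. Without OX390 mock replicate 3 the adjusted p became 0.525 for nitrate, 0.193 for sugar transporters and 0.441 for chloroplast transcripts, and without OX390 mock replicate 1 it became 0.154 for glucanases, 0.0663 for sugar transporters, 0.0747 for aquaporins and 0.505 for lipid transfer proteins. Without OX390 inoculated replicate 1 the values in the order nitrate, aquaporins, glucanases, lipid transfer, sugar and chloroplast were 0.0556, 0.0871, 0.0871, 0.0501, 0.455 and 0.857.

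The OX390 effect in mock roots asks what the miR390 vector changed without rhizobia. The list of nitrate uptake and reduction genes was higher in OX390 roots, with 11 of 11 members positive (median 1.30, camera adjusted p = 2.80e-05, adjusted p = 0.763 with an estimated correlation). MtNRT2.1 lay at 3.94 ± 2.19 CPM in EV and 68.8 ± 87.3 CPM in OX390 roots, MtNRT2.2 at 2.89 ± 1.75 and 51.7 ± 65.0 CPM, MtNAR2.2 at 51.1 ± 7.29 and 134 ± 91.2 CPM, and MtNRT2.3 at 21.1 ± 1.25 and 45.8 ± 25.8 CPM. The list was no longer called without OX390 mock replicate 3 (0.292), which held 3391 counts of MtNRT2.1 against 122 in replicate 1, or without EV mock replicate 1 (0.366). Fermentation and phytoglobin genes were higher as a list, with 7 of 7 positive (median 0.59, camera adjusted p = 0.0167, adjusted p = 0.763 with an estimated correlation), with MtPhytogb1.1 at 51.6 ± 4.26 and 119 ± 81.3 CPM, and were no longer called without EV mock replicate 1 (0.451) or OX390 mock replicate 3 (0.674). Lipid transfer proteins were higher as a list, with 36 of 44 positive (median 0.42, camera adjusted p = 2.80e-05, adjusted p = 0.763 with an estimated correlation; 0.153 without EV mock replicate 1 and 0.158 without OX390 mock replicate 1), with MtnsLTP60 at 192 ± 26.99 and 302 ± 42.0 CPM. Class III peroxidases were higher as a list, with 58 of 79 positive (median 0.25, camera adjusted p = 0.00797, adjusted p = 0.862 with an estimated correlation), with MtPrx08 at 11.4 ± 0.782 and 21.6 ± 1.40 CPM and MtPrx27 at 51.1 ± 2.82 and 27.2 ± 0.428 CPM. Their call was lost without EV mock replicate 1 (0.766) and without OX390 mock replicate 1 (0.865, with the camera direction turned and a median of 0.03). With edgeR 0 members of these 4 lists passed adjusted over the list alone or over all entries, and in the order given 5, 1, 3 and 3 were higher at an unadjusted p under 0.05. Of all entries, 3.30% met that threshold in this contrast, in either direction.

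The Nod factor list was higher in OX390 mock roots, with 18 of 26 positive (median 0.19, camera adjusted p = 0.0477, adjusted p = 0.763 with an estimated correlation), with MtNFP at 5.36 ± 2.70 and 12.04 ± 1.104 CPM and MtERN2 at 6.15 ± 1.94 and 12.4 ± 2.98 CPM. It lost its call without EV mock replicate 1 (0.640), EV inoculated replicate 1 (0.0796), EV inoculated replicate 3 (0.0792), OX390 mock replicate 3 (0.544) and OX390 inoculated replicate 3 (0.0513). Chloroplast-encoded transcripts were lower as a list, with 69 of 73 negative (median −1.67, camera adjusted p = 4.01e-07), as were mitochondrion-encoded transcripts, with 109 of 114 (median −1.05, camera adjusted p = 1.03e-05), both with adjusted p = 0.862 with an estimated correlation. Without EV mock replicate 1 the camera direction of both turned (0.893 and 0.909, medians 0.15 and 0.15), and without OX390 mock replicate 3 neither list was called (0.139 and 0.637). MtCKX2 had 0 counts in EV mock and 13 and 18 counts in OX390 mock, at least 10.8-fold higher, and was the member of the cytokinin list that passed adjusted over that list alone. In these 3 lists, of Nod factor genes and organelle transcripts, 0 members passed in either adjustment. Chosen after their values were seen, the 4 entries that edgeR called were those called in OX390 roots, MtrunA17Chr6g1025401 higher and MSTRG.14225, MSTRG.26939 and MtrunA17Chr6g0463451 at 0 counts in OX390 mock (adjusted p = 0.0398 for each). The locus sum of MtrunA17Chr6g0463451 differed by 0.03 on the log2 scale. The share of entries at an unadjusted p under 0.05 was 3.30%, below the 5% that chance alone gives. There were 1148 entries at an unadjusted p under 0.05, DESeq2 called 378 and limma-voom 0, and edgeR called 1 without OX390 mock replicate 3 and 0 without any other library. As locus sums edgeR called MtrunA17Chr6g1025401, DESeq2 63 and limma-voom 0, and edgeR called 2 without EV mock replicate 1, 4 without EV mock replicate 3 and 0 without either EV inoculated or either OX390 mock library.

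The OX390 effect in inoculated roots asks what the vector changed in the presence of rhizobia. The list of phenylpropanoid and flavonoid synthesis genes was higher in OX390 roots, with 17 of 18 members positive (median 0.51, camera adjusted p = 7.21e-05, adjusted p = 0.948 with an estimated correlation). The chalcone isomerase gene MtCHI-2 lay at 443 ± 60.2 CPM in EV and 687 ± 61.0 CPM in OX390 roots, MtCYP81E7 at 447 ± 18.2 and 601 ± 18.2 CPM, and the isoflavone reductase gene MtIFR at 305 ± 37.3 and 458 ± 4.13 CPM. Lipid transfer proteins were higher as a list, with 34 of 44 positive (median 0.24, camera adjusted p = 0.0243), with MtnsLTP100 at 23.7 ± 5.69 and 40.0 ± 4.23 CPM, and so were class III peroxidases, with 52 of 79 positive (median 0.14, camera adjusted p = 0.0243), with MtPrx08 at 7.97 ± 0.590 and 14.7 ± 1.66 CPM. Chloroplast-encoded transcripts were higher as a list, with 61 of 73 positive (median 0.81, camera adjusted p = 2.04e-04). Each of these 3 lists had adjusted p = 0.948 with an estimated correlation, and 0 members of the 4 lists passed adjusted over the list alone or over all entries. Without OX390 inoculated replicate 3 the adjusted p was 0.0524 for flavonoid genes, 0.344 for peroxidases and 0.235 for lipid transfer proteins. Without EV inoculated replicate 1 it was 0.652 for peroxidases and 0.550 for lipid transfer proteins, without OX390 inoculated replicate 1 it was 0.122 for lipid transfer proteins and 0.927 for chloroplast transcripts, and without EV inoculated replicate 3 the camera direction of chloroplast transcripts turned (0.310, median 0.08). As entries edgeR called 0 (785, or 2.25%, at an unadjusted p under 0.05), DESeq2 221 and limma-voom 0. As locus sums edgeR called MtrunA17Chr6g1025401, at 0 counts in OX390 inoculated roots, DESeq2 27 and limma-voom 0, and edgeR called 2 without EV mock replicate 1 or OX390 inoculated replicate 1 and 0 without either EV inoculated library, either OX390 mock library or OX390 inoculated replicate 3.

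The average OX390 effect compares the 4 OX390 with the 4 EV libraries. The list of lipid transfer proteins was higher in OX390 roots, with 39 of 44 members positive (median 0.36, camera adjusted p = 1.31e-05, adjusted p = 0.881 with an estimated correlation). The camera call held without each library in turn, but fry did not call the list (fry adjusted p = 0.810). MtnsLTP60 lay at 199.6 ± 19.2 CPM in EV and 284 ± 31.9 CPM in OX390 libraries. Class III peroxidases were higher as a list, with 63 of 79 positive (median 0.16, camera adjusted p = 8.13e-04, adjusted p = 0.933 with an estimated correlation), with MtPrx08 at 9.66 ± 2.03 and 18.2 ± 4.15 CPM. Flavonoid genes were higher as a list, with 16 of 18 positive (median 0.26, camera adjusted p = 0.00175, adjusted p = 0.881 with an estimated correlation), with Mt4CL-3 at 45.8 ± 4.57 and 67.4 ± 10.5 CPM. Also higher as lists were nitrate genes with 11 of 11 positive (median 0.57, camera adjusted p = 0.00686) and aquaporins with 6 of 7 (median 0.12, camera adjusted p = 0.0200), and mitochondrion-encoded transcripts were lower as a list, with 108 of 114 negative (median −0.65, camera adjusted p = 0.00630), each with adjusted p = 0.933 with an estimated correlation. Of the members of these 6 lists, MtTIP1g passed adjusted over its list alone, and 0 over all entries. Its log2 difference was −0.18 (SE 0.72) in mock roots, and in inoculated roots it was at least 13-fold higher in OX390 than in EV (adjusted p = 0.0112 over the list alone). MtCKX2 passed adjusted over the cytokinin list alone, at 1.46 ± 1.69 CPM in EV and 3.82 ± 4.12 CPM in OX390 libraries. Both passes rest on a group at 0 counts, EV inoculated for MtTIP1g and EV mock for MtCKX2. Neither is corrected over lists and contrasts, so chance is not excluded. MtSRL1 lay at 4.02 ± 3.26 and 8.17 ± 4.56 CPM.

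Without EV mock replicate 1 the adjusted p of this comparison became 0.339 for peroxidases, 0.501 for nitrate, 0.537 for aquaporins and 0.948 for mitochondrial transcripts, whose camera direction turned while the median stayed negative (−0.09). Without OX390 mock replicate 1 it became 0.392 for peroxidases and 0.397 for aquaporins. Without OX390 mock replicate 3 it became 0.158 for flavonoid genes, 0.659 for nitrate and 0.777 for mitochondrial transcripts. Without OX390 inoculated replicate 3 it became 0.0782 for flavonoid genes, 0.128 for nitrate, 0.124 for aquaporins and 0.802 for mitochondrial transcripts. Without EV inoculated replicate 1 it became 0.0916 for aquaporins, and mitochondrial transcripts passed in the other direction (0.0267, median 0.33). The aquaporin call was also lost with the stricter filter (0.133). With edgeR 0 entries were called (1229, or 3.53%, at an unadjusted p under 0.05), DESeq2 340 and limma-voom 0. With edgeR 0 locus sums were called (1036, or 3.94%, at an unadjusted p under 0.05), DESeq2 66 and limma-voom 0. Leaving out OX390 mock replicate 3 gave 1 entry, and leaving out either EV mock library gave 1 locus sum. MtSUNN differed by 0.20 (SE 0.46), MtCHK1/MtCRE1 by −0.01 (SE 0.51) and MtRRA4;MtRR4 by 0.24 (SE 0.23) on the log2 scale, with MtSUNN turning to −0.15 without EV mock replicate 1 and MtCHK1/MtCRE1 to 0.87 without EV mock replicate 3. MtCLE13 had 0 to 20 counts per library and was not tested.

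The interaction asks whether the inoculation response differed between the vectors. For the nitrate genes it did in the camera test, with 10 of 11 members negative (median −1.22, camera adjusted p = 8.10e-04, adjusted p = 0.858 with an estimated correlation). MtNRT2.1 lay at 3.94 CPM in mock and 5.77 CPM in inoculated EV roots, and at 68.8 and 3.98 CPM in OX390 roots. That call was lost without EV mock replicate 1 (0.285), OX390 mock replicate 3 (0.182) and OX390 inoculated replicate 1 (0.0654). The lists of chloroplast-encoded transcripts, with 69 of 73 members positive (median 2.49, camera adjusted p = 2.29e-11, adjusted p = 0.858 with an estimated correlation), and mitochondrion-encoded transcripts, with 103 of 114 positive (median 0.74, camera adjusted p = 8.10e-04, adjusted p = 0.991 with an estimated correlation), also passed. The chloroplast median was 0.66 without EV mock replicate 1 (adjusted p = 0.0428). The mitochondrial call was lost without EV mock replicate 1 (0.982), OX390 mock replicate 3 (0.717), OX390 inoculated replicate 1 (0.656) and EV inoculated replicate 3 (0.0816, with the camera direction turned and a median of −0.01). The Nod factor and nodulin lists did not pass, and 0 members of the 3 called lists passed in either adjustment. As an entry, edgeR called MtrunA17Chr6g1025401, chosen after its values were seen, at 103 ± 11.7 CPM in EV inoculated and 117 ± 4.36 CPM in OX390 mock libraries and at 0 counts in the other 4 (adjusted p = 0.0430). There were 855 entries at an unadjusted p under 0.05, DESeq2 called 246 and limma-voom 0, and edgeR called 2 without EV mock replicate 3, 1 without OX390 mock replicate 3 and 0 without each of the other 6. As locus sums edgeR called the same gene, DESeq2 23 and limma-voom 1, and edgeR called 3 without EV mock replicate 3, 2 without OX390 inoculated replicate 1 and 0 without either OX390 mock library.

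Across genes, the inoculation responses of EV and OX390 roots correlated with Pearson r = 0.0975 and Spearman rho = 0.262 over 34837 entries, and 0.240 and 0.437 over 26263 locus sums. Genes are not independent replicates, so no p is given. The correlation covers all tested genes, few of which were called, and the spread between libraries lowers it. The value that equal responses would give with this spread was not computed. A low value therefore does not show that the vectors respond differently. As entries, the Pearson value ranged from 0.0442 without EV mock replicate 3 to 0.127 without EV mock replicate 1. It was 0.0510 without EV inoculated replicate 1 and 0.0611 without OX390 inoculated replicate 3.

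**Figure D2:**
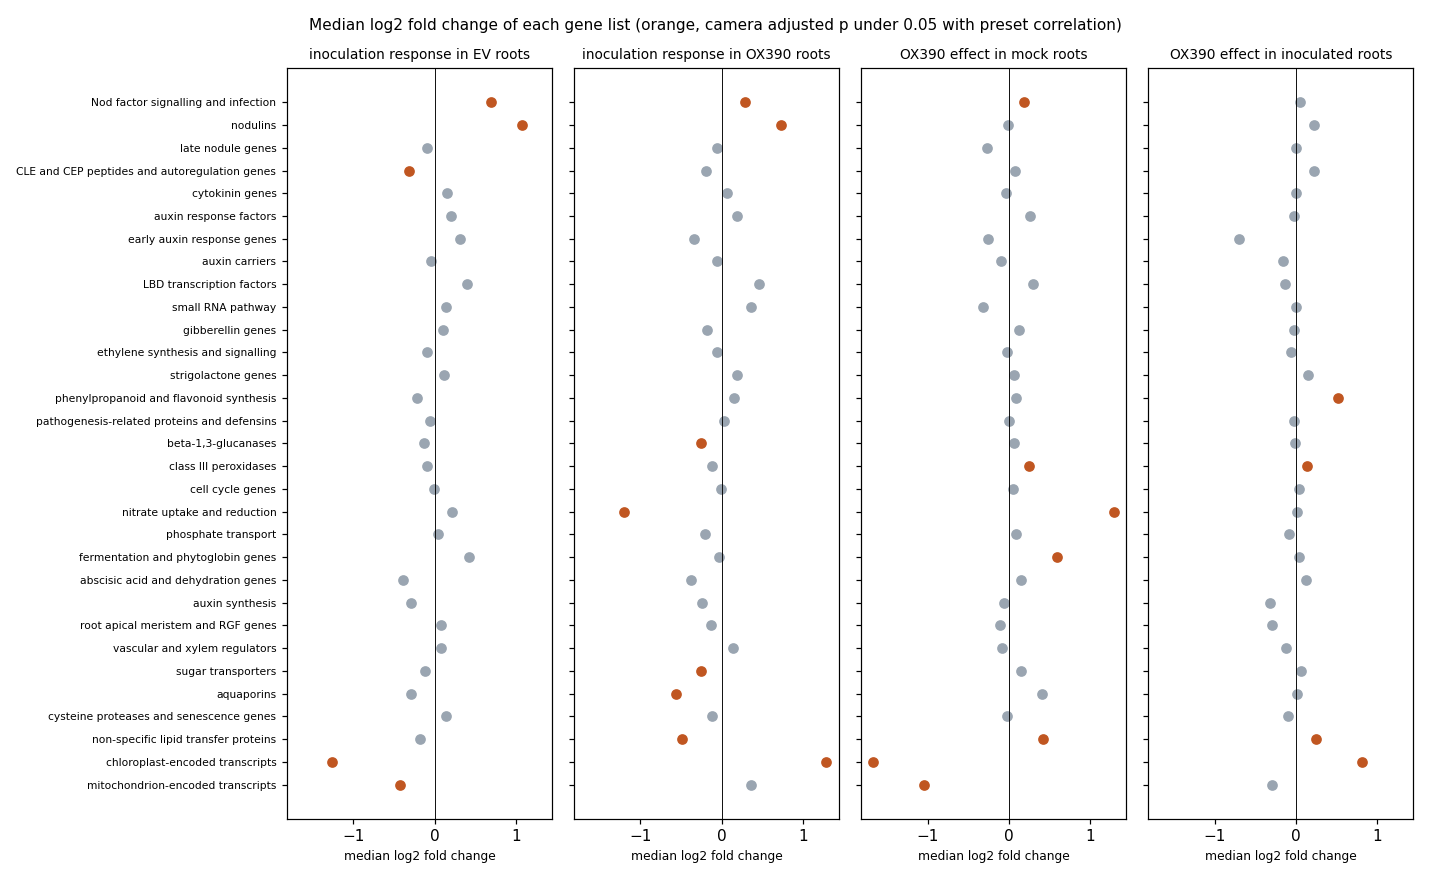
Median log2 fold change of the tested members of each gene list (horizontal axis) in the 4 comparisons of 2 groups, 1 point per list; orange points have a camera adjusted p under 0.05 with the preset correlation. The Nod factor and nodulin medians lie right of 0 in both inoculation comparisons, at 0.69 and 1.08 in EV and 0.29 and 0.73 in OX390 roots.

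As entries, the other 18 lists passed camera in none of the 7 contrasts. Their lowest adjusted p was 0.0652 for the small RNA pathway and for pathogenesis-related proteins and defensins, 0.0686 for auxin response factors and for LBD transcription factors, 0.0703 for strigolactone genes, 0.123 for late nodule genes and for gibberellin genes, and 0.190 for abscisic acid and dehydration genes and for auxin synthesis. It was 0.388 for early auxin response genes and for ethylene synthesis and signalling, 0.391 for cytokinin genes, 0.412 for cell cycle genes, 0.424 for vascular and xylem regulators, 0.440 for root apical meristem and RGF genes, 0.522 for phosphate transport, and 0.592 for auxin carriers and for cysteine proteases and senescence genes. Arbuscular mycorrhiza genes had 3 tested members of 12 and were not tested as a list. Upon inoculation over both vectors, MtD27, MtD27L and MtMAX1a of the strigolactone list rose adjusted over the list alone, as did MtCKX2 of the cytokinin list and MtCHIT5b and MtPDF10 of the defence list, and MtSAUR1 of the early auxin list fell, with 0 of them over all entries.

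As locus sums, a unit chosen after seeing the data, camera called 55 pairs of list and contrast, the 39 called as entries among them in the same direction, and 3 of the 18 lists above passed. The small RNA pathway list was lower in OX390 mock roots, with 10 of 10 members negative (median −0.26, camera adjusted p = 0.00461, adjusted p = 0.667 with an estimated correlation). It was also lower over both states, with 8 of 10 negative (median −0.20, camera adjusted p = 0.0229, adjusted p = 0.769 with an estimated correlation), and rose upon inoculation in OX390 roots, with 8 of 10 positive (median 0.28, camera adjusted p = 0.0167, adjusted p = 0.622 with an estimated correlation). Without OX390 mock replicate 1 these 3 values became 0.729, 0.613 and 0.596. The first was also lost without EV mock replicate 1 (0.255) and replicate 3 (0.0529), and the second without EV mock replicate 1 (0.209), EV inoculated replicate 3 (0.0625) and OX390 inoculated replicate 3 (0.0816). LBD transcription factors rose as a list in EV roots, with 5 of 5 positive (median 0.38, camera adjusted p = 0.0401, adjusted p = 0.622 with an estimated correlation). That was lost without EV mock replicate 1 (0.0926) or 3 (0.226), EV inoculated replicate 3 (0.486), and OX390 mock replicate 1 (0.0752) or 3 (0.0749). Late nodule genes were lower as a list over both states, with 15 of 20 negative (median −0.14, camera adjusted p = 0.0262, adjusted p = 0.528 with an estimated correlation). This was lost without EV mock replicate 1 (0.220), EV inoculated replicate 1 (0.173), OX390 mock replicate 1 (0.0912) or 3 (0.196), and OX390 inoculated replicate 3 (0.0713). With edgeR 0 members of these 3 lists passed as locus sums in these contrasts, adjusted over the list alone or over all loci.

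The other calls found as locus sums alone are of lists called elsewhere as entries, and each was lost without at least 2 of the libraries. They include flavonoid genes in the interaction, with 13 of 17 positive (median 0.47, camera adjusted p = 2.89e-04, adjusted p = 0.921 with an estimated correlation), lost without OX390 mock replicate 1 (0.101) and OX390 inoculated replicate 3 (0.0616). Nod factor genes were higher as a list over both states in OX390 roots, with 23 of 28 positive (median 0.14, camera adjusted p = 0.00235, adjusted p = 0.528 with an estimated correlation), lost without EV mock replicate 1 (0.101) and OX390 mock replicate 3 (0.192).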

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

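The tests of called entries and of MtrunA17Chr6g1025401 were chosen after the results were seen, while those of entries at 0 in a pair of libraries and of chloroplast transcripts without EV mock replicate 1 were written before. No group has the 4 libraries that a test for an outlying library needs. The inoculation response differed between vectors, by the test of the interaction, for MtrunA17Chr6g1025401 (edgeR adjusted p = 0.0430) and in camera, as entries, for 3 gene lists. These were nitrate uptake and reduction with a median of −1.22 on the log2 scale, chloroplast-encoded transcripts with 2.49 and mitochondrion-encoded transcripts with 0.74. None of the 3 was called with an estimated correlation (adjusted p = 0.858, 0.858 and 0.991 with an estimated correlation). The nitrate call was also lost without EV mock replicate 1 (0.285), OX390 mock replicate 3 (0.182) and OX390 inoculated replicate 1 (0.0654), and the mitochondrial call without these 3 libraries (0.982, 0.717 and 0.656) and EV inoculated replicate 3 (0.0816).

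MtrunA17Chr6g1025401 had 0 counts in both EV mock and both OX390 inoculated libraries, and 103 ± 11.7 and 117 ± 4.36 CPM in EV inoculated and OX390 mock roots. With EV and OX390 labels exchanged in one inoculation state, loci that differ between the vectors would be parted in this pattern, and 0 other loci are parted so against 13 as EV from OX390. As 7 of the 35 splits of the 8 libraries part at least 13 loci, a real difference between the vectors is not shown by this count, and the exchange stays open. The locus may also owe its pattern to reads counted at another locus in the other 4 libraries: 2 loci are higher there by enough CPM, but 51 of the 69 other choices of 4 libraries give as many, so this stays open and cannot be told apart from chance. A biological switch between the vectors was not tested by any independent value.

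The second pattern concerns called entries at 0 in both libraries of a group, such as MSTRG.14225, MSTRG.26939 and MtrunA17Chr6g0463451 in OX390 mock roots. All 6 called entries of loci with several entries have locus sums that changed by under 1 on the log2 scale, as reads assigned to another entry of the same locus could give. For the 3 called entries that are alone in their locus, which are MtrunA17Chr6g1025401, MtrunA17Chr8g0354001 and MtrunA17Chr1g0200491, this is excluded. In loci with several entries, 93 entries are at 0 in a pair of libraries and at 5 CPM or more in the other 6. Of these, 10.8% have both in the same group (exact 95% interval 5.28% to 18.9%), where random placing gives 14.3%. With no excess, this argues against transcript forms missing from a single group, for these entries as a set. A form that changes with inoculation or vector alone would be at 0 in more libraries, so this count does not cover it. A change of transcript form in any single locus stays open.

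The chloroplast interaction is the third pattern. Without EV mock replicate 1, which has the highest chloroplast share (0.0644%), the list median went from 2.49 to 0.663, as predicted if this library carried the pattern. That fit leaves EV mock replicate 3 alone against both EV inoculated libraries, so it also carries the difference between numbers 1 and 3. On log2 CPM the list median was 2.62 within number 1. Within number 3, where EV mock replicate 1 plays no part, it was 1.53. The sign was thus the same in both numbers, and how much of the size rests on this library stays open. Each of these values rests on a single library per group, so a difference by number that varies between groups has no test. A difference in organelle RNA between roots of the vectors stays open and untested.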

How the results depend on the processing

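The locus sums, their alternatives and the fit on named entries alone were chosen after seeing the data. Calls of edgeR for entries are in the order inoculation in EV, inoculation in OX390, OX390 in mock, OX390 in inoculated roots, interaction, average OX390 and average inoculation, with 0, 4, 4, 0, 1, 0 and 8. DESeq2 gave 658, 374, 378, 221, 246, 340 and 876, and 400, 122, 63, 27, 23, 66 and 563 as locus sums. limma-voom gave 0 for each as entries, and 0 as locus sums in the first 4 contrasts. DESeq2 size factors gave 2 for inoculation in EV. No filter gave 3, 2 and 4 for inoculation in EV, the interaction and average OX390. A stricter filter gave 3, 3, 5 and 5 for inoculation in EV, OX390 in inoculated roots, the interaction and average OX390. Named entries alone gave 3, 2, 2, 3, 4 and 2 in the first 6. Locus sums gave 1 for inoculation in EV, OX390 in mock and OX390 in inoculated roots, and 24 for average inoculation. The libraries of 2 groups alone gave 0 for inoculation in OX390 and OX390 in mock, and an additive model 1 and 0 for the averages. With the replicate number as a block, entries gave 0 in each contrast, locus sums 0 in the first 4 and 4 for average inoculation. The log2 CPM difference between libraries 1 and 3 of a group was correlated, across genes, with that of each other group. The values lay between −0.0931 and 0.145 as entries and between −0.223 and 0.346 as locus sums. Both lowest values are of EV mock with OX390 mock, and all other pairs of groups were positive. As not every pair goes together, the main fits do not pair the libraries by number. This does not exclude a difference by number that most groups share. With the block, average inoculation went from 24 to 4 locus sums and from 8 to 0 entries. The split by replicate number still parts 92 loci, where the median of the 35 splits is 4 and inoculation parts 102, so the libraries also differ by number. Leaving out 1 library gave 0, 0 to 2, 0 to 1, 0, 0 to 2, 0 to 1 and 0 to 1 calls as entries, and 0 to 186, 0 to 16, 0 to 4, 0 to 2, 0 to 3, 0 to 1 and 0 to 158 as locus sums. The gene list calls were 39, with 0 with an estimated correlation, 6 with fry, 55 as locus sums, 43 with the block (where the Nod factor list for OX390 in mock had 0.0523) and 31 to 53 leaving out 1 library. Without 1 library the camera adjusted p ranged from 2.87e-04 to 0.896 for CLE and CEP peptides in EV roots, 5.82e-18 to 0.772 for chloroplast transcripts in EV roots, 1.26e-28 to 0.679 for mitochondrial transcripts in EV roots, 2.13e-05 to 0.865 for peroxidases in OX390 against EV mock, 5.56e-15 to 0.893 for chloroplast and 6.54e-10 to 0.909 for mitochondrial transcripts in the same, 1.05e-16 to 0.927 for chloroplast transcripts in OX390 against EV inoculated roots, and 5.88e-23 to 0.982 and 2.67e-18 to 0.948 for mitochondrial transcripts in the interaction and the average OX390 effect. Lipid transfer proteins turned in fry for average inoculation (0.879). In the average OX390 effect, MtARF12; MtARF4a gave −0.26 as a locus sum and −0.12 to 5.35 leaving out 1 library, MtARF2 −0.15 as a locus sum, MtARF2;MtARF23 −0.22 to 0.0544, MtSUNN −0.15 to 0.90, MtNF-YA1 −0.16 to 0.40 and MtCHK1/MtCRE1 −0.39 to 0.87 leaving out 1 library, with 0.22 for MtCHK1/MtCRE1 in limma-voom and 0.12 with the block. As locus sums, MtNF-YA2 gave −0.0594 for average inoculation and MtrunA17Chr6g0463451 0.0295 for OX390 in mock. The correlation of responses was 0.0975, with 0.240 as locus sums and 0.0442 to 0.127 leaving out 1 library. The cause of each change was not tested, except that fewer libraries were fitted where some were left out.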

Other observations

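Adjusted over their lists alone, further genes rose upon inoculation over both vectors in edgeR. The flotillin gene MtFLOT4, of the infection list, changed by 0.80 (SE 0.20) on the log2 scale. In the strigolactone list, MtMAX1a changed by 0.65 (SE 0.13) and MtD27L by 1.49 (SE 0.39), beside MtD27. The early auxin response gene MtSAUR1 fell, with −0.89 (SE 0.18). None of these passed over all entries.

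The counts of other splits were chosen after the results were seen. The 8 libraries can be split into 4 and 4 in 35 ways, each fitted here with edgeR as 1 factor. As locus sums, the inoculated and mock libraries gave 35 calls, and the real split alone reached this (1 of 35). The highest of the others, the split by replicate number, gave 6. With 35 splits no rank can go beyond 1 of 35, and the count was chosen after seeing the results, so chance is not excluded. By this count of calls the inoculation split still stands apart from the others. Counted at an unadjusted p under 0.05, the same split had 2976 loci, 5 of 35 splits, itself included, reached this, the split by replicate number among them (2989), and the highest other had 6018. Chance cannot be excluded for that count, and the libraries have a structure beyond the groups. As entries they gave 5 calls, 2 of 35 splits reached this, and the split by replicate number also gave 5, so chance cannot be excluded. OX390 against EV gave 1 call as entries, where 15 of 35 splits gave as many and the highest other gave 5, so chance cannot be excluded. It gave 0 calls as locus sums (926 loci at an unadjusted p under 0.05), which all 35 of 35 splits reach whatever the data, with 35 in the highest other, the inoculation split, so that count says nothing about chance.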
